A study of Homo sapiens with 8 samples.

How the data were processed

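FoxA1 binding was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in HuH7, a human hepatocellular carcinoma cell line. The study held 8 libraries: 3 FoxA1 immunoprecipitations from asynchronously cycling cells, 3 from mitotic cells, and 1 input library (chromatin DNA without immunoprecipitation) from each condition. Per the labels' protocols, mitotic cells were held in S phase with 2 mM thymidine for 24 h and then moved to nocodazole, a microtubule poison, at 0.06 µg/mL for 18 h, which left about 94% of the cells in metaphase. The protocol states that these blocked cells were used for the immunoprecipitation, whereas the source label of the same samples names them as blocked and released. The labels conflict on this point. Each immunoprecipitation started from 335 µg of material, per the labels' protocols.

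The authors deposited 1 peak list per condition, and both lists are described as merged per the file headers. How the libraries or their peaks were merged, the read aligner, the peak caller and the calling threshold are not given in the sources used here. The genome build was hg18, per the submitters' processing notes. Each list holds the chromosome, start and end of each peak. The score field is 0 for all peaks of both deposited lists and the strand is always plus, so neither carries information. Read depth is therefore unknown, the input libraries and the single immunoprecipitations were not analysed here as separate values, and no value has an SD between libraries. The tests below have peaks as their units, and their intervals cover counting over peaks only, not the variation between cultures or library preparations.

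Positions were converted to 1-based coordinates. The main tests were planned before the data were examined, with peak width to be used where the lists gave no score. The midpoint target of 100 bp, the removal of mitotic peaks near another, the stratification by width quartile and the analysis of where a mitotic peak lies inside its asynchronous peak were chosen after seeing the data. Width therefore stands in throughout for the peak height or significance that the lists lack. The edges of a merged peak depend on fragment length, depth and the rule for merging, so width is a weak substitute. Peaks counted as shared when they had at least 1 bp in common, and the counts were checked with bedtools 2.31.1. Shares carry exact Clopper-Pearson 95% intervals. Chance overlap was estimated by 100000 random rotations of the mitotic peaks within each chromosome, over the span covered by both lists. These rotations keep the spacing of the mitotic peaks but do not account for mappability or open chromatin. Medians were compared by two-sided permutation tests with 100000 resamples, and the interval of a difference in medians came from 10000 bootstrap resamples of peaks. The smallest p these resamples can give is 1e-05. Shares were compared by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the 23 chromosomes tested. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, and plots used matplotlib 3.10.9. On simulated data, all 400 of 400 mitotic peaks placed at midpoints of the 3509 asynchronous peaks were recovered. Peaks placed there must overlap, so this checks the counting only and not the sensitivity of the peak lists.

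The regions named below follow a rule of widths: the 10 widest shared asynchronous peaks, the 5 widest asynchronous peaks without a mitotic overlap, the 5 widest mitotic peaks without an asynchronous overlap, and the 3 clusters with most asynchronous peaks when peaks within 10 kb are chained. Of the chromosomes, those past the adjusted threshold of 0.05 are named, with the highest and the lowest share among chromosomes with at least 50 asynchronous peaks. Other overlap definitions, keeping only peaks at or above the median width of a list, merging within lists and leaving out the sex chromosomes were tried as alternatives. Gene locations, sequence motifs and the planned gene lists were not used here, because no hg18 annotation or sequence was used and coordinates were not carried between builds.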

Results

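FoxA1 is a pioneer transcription factor of the forkhead family that can bind its sites in compact chromatin. Its binding was mapped in HuH7 hepatocellular carcinoma cells that were either cycling asynchronously or blocked in mitosis, to ask which of its interphase sites are also bound on mitotic chromosomes. Each condition had 3 immunoprecipitated libraries and 1 input library, and the data compared here are 1 merged peak list per condition. All positions are in hg18. The lists give positions without heights, so the read depth behind each peak is unknown, and each count of peaks is a single value with no replicate list.

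The mitotic list held fewer and narrower FoxA1 peaks than the asynchronous list. The asynchronous list held 3509 peaks and the mitotic list 544, a ratio of 6.45. The median peak width was 649 bp in asynchronous cells (quartiles 527 and 766 bp) and 206 bp in mitotic cells (quartiles 174 and 241.5 bp), a ratio of 3.15. The asynchronous peaks covered 2.385 Mb and the mitotic peaks 0.119 Mb, a ratio of 20.01 that combines the lower number with the smaller width. Asynchronous peaks ranged from 208 to 4496 bp and mitotic peaks from 53 to 2299 bp. No test was made of the numbers or widths between conditions, because each condition has 1 list.

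**Figure D1:**
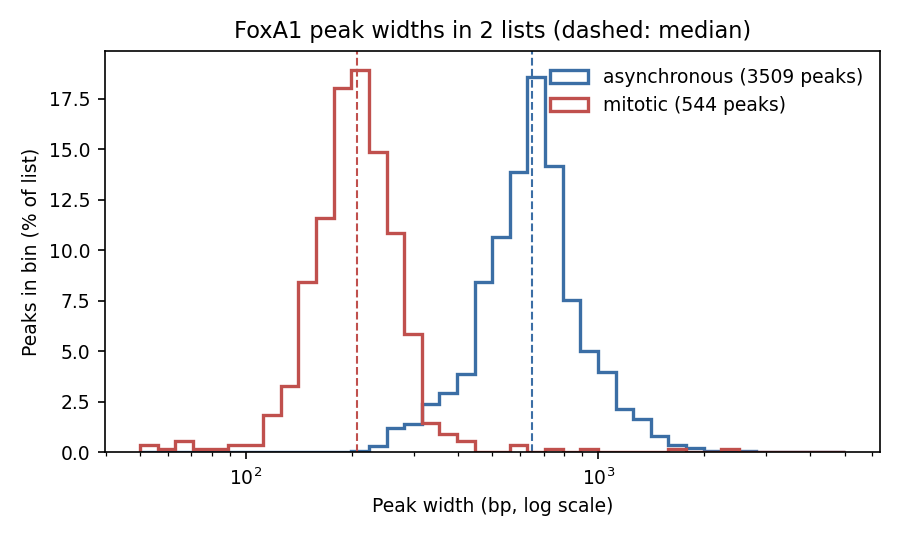
Distribution of FoxA1 peak widths (x axis, bp, log scale) as the percentage of each list per bin (y axis) for the 3509 asynchronous and the 544 mitotic peaks, with dashed lines at the medians. The mitotic median of 206 bp lies below the asynchronous median of 649 bp.

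Most mitotic peaks lay on sites that were also bound in asynchronous cells. Of the 544 mitotic peaks, 457 overlapped an asynchronous peak (84.0%, 95% interval 80.7 to 87.0). In the other direction, 458 of the 3509 asynchronous peaks overlapped a mitotic peak (13.1%, 95% interval 12.0 to 14.2), while 3051 did not. Random rotation of the mitotic peaks along their chromosomes gave 0.649 overlapping peaks on average and 35 at most, against the 457 observed (one-sided permutation test, p = 1e-05, the smallest that 100000 rotations can give). The rotations could by chance be very small and so return a chromosome's peaks to their real positions. The highest count of 35 may therefore not be chance overlap alone. The share of asynchronous peaks counts only sites that passed the authors' calling in mitotic cells, and a site below their threshold counts as not overlapping.

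Taken as a set, the mitotic peaks sat nearer the centres of the asynchronous peaks than random placement would put them. The analysis was chosen after seeing the data. The overlapping peaks formed 460 pairs, since 3 mitotic peaks each touched 2 asynchronous peaks and 2 asynchronous peaks each touched 2 mitotic peaks. The mitotic peak lay wholly inside the asynchronous peak in 458 of the 460 pairs (99.6%). Overlapping pairs of these widths placed at random would give 55.1%. The median distance between the midpoints of a pair was 49.25 bp (quartiles 23 and 100.1 bp). Among the 458 contained pairs it was 48.75 bp, against a mean of 123.7 bp and a lowest value of 98.8 bp over 10000 random placements inside the same asynchronous peaks (one-sided permutation test, p = 1e-04, the smallest these placements can give). The mitotic peak spanned a median of 28.6% of the asynchronous peak (quartiles 23.5% and 34.7%).

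**Figure D2:**
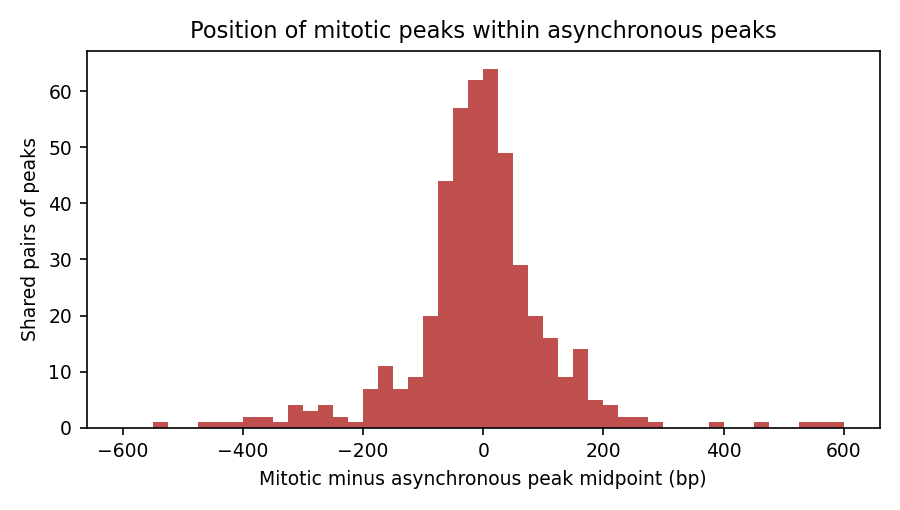
Distance from the midpoint of the asynchronous peak to the midpoint of the overlapping mitotic peak (x axis, bp) for 460 shared pairs (y axis, number of pairs per 25 bp bin). The distances centre near 0, with a median absolute distance of 49.25 bp.

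Asynchronous peaks that were shared with mitotic cells were wider than those that were not. The median width was 716.5 bp for the 458 shared peaks (quartiles 635 and 871.5 bp) and 636 bp for the 3051 others (quartiles 514 and 752 bp), a difference of 80.5 bp (95% interval 64.5 to 93.5, permutation test, p = 1e-05, the smallest possible). It was 39 bp when only midpoints within 100 bp counted as shared, a target chosen after seeing the data that does not grow with the peak (permutation test, p = 0.00081). The overlapping share was 4.67% in the narrowest quartile (41 of 878 peaks, 95% interval 3.37 to 6.28) and 10.3% in the second (91 of 881, 8.40 to 12.5). It was 18.4% in the third quartile (161 of 874, 15.9 to 21.1) and 18.8% in the widest (165 of 876, 16.3 to 21.6). The widest and narrowest quartiles differed with an odds ratio of 4.73 (95% interval 3.29 to 6.94, Fisher's exact test, p = 3.08e-21). With the same target of 100 bp, chosen after seeing the data, the odds ratio was 1.82 (95% interval 1.18 to 2.84, Fisher's exact test, p = 0.00424). That target leaves out mitotic peaks inside a wide asynchronous peak but far from its midpoint, so it can lower both the 39 bp and this odds ratio by construction.

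**Figure D3:**
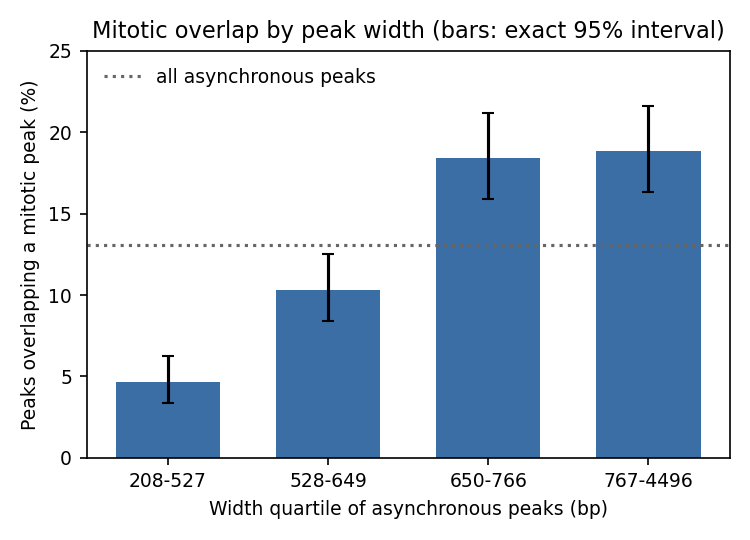
Share of asynchronous FoxA1 peaks that overlap a mitotic peak (y axis, %) in quartiles of asynchronous peak width (x axis, bp), with exact 95% intervals. The dotted line marks the 13.1% of all asynchronous peaks, and the share was 4.67% in the narrowest and 18.8% in the widest quartile.

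Wide asynchronous peaks were nevertheless mostly without a mitotic peak. Among the 544 widest asynchronous peaks, as many as there are mitotic peaks and each at least 877 bp wide, 114 overlapped a mitotic peak (21.0%) and 430 did not. These 544 peaks accounted for 115 of the 544 mitotic peaks (21.1%, 95% interval 17.8 to 24.8), against 71.2 on average and 107 at most over 100000 random draws of as many asynchronous peaks (one-sided permutation test, p = 1e-05, the smallest possible). That excess uses the same overlaps and widths as the comparison of shared and other peaks above, so it is not separate evidence. Across the 460 shared pairs, the widths in the 2 lists were related, with a Spearman rho of 0.37 (permutation p = 1e-05) and a Pearson r of 0.28 (permutation p = 0.00227). Without the 2 pairs farthest from the median asynchronous width, r was 0.35 and rho 0.38 (permutation p = 1e-05 for both). That drop went by asynchronous width, so the pair with a mitotic peak of 1722 bp stayed in. The relation was not recomputed without that pair. These relations are across peaks, which are not independent replicates.

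The widest shared asynchronous peak was a 4496 bp region of chromosome 14 (31620763 to 31625258), within which the mitotic peak spanned 182 bp. The next were on chromosome 20 (22357936 to 22359928), chromosome 14 (30767260 to 30769212), chromosome 11 (67670117 to 67671989) and chromosome 20 (19943102 to 19944972). Their widths were 1993, 1953, 1873 and 1871 bp, and their mitotic peaks spanned 248, 293, 284 and 232 bp. A 1837 bp peak on chromosome 14 (37130095 to 37131931) differed from the others, because its mitotic peak was 1722 bp wide, equal to 93.7% of the asynchronous width against a median of 28.6% over all pairs. Whether this peak coincides with an exon was not examined. The remaining 4 of the 10 widest were on chromosome 1 (143703642 to 143705332 and 8241396 to 8243027), chromosome 5 (124024878 to 124026500) and chromosome 7 (55022804 to 55024386). They spanned 1691, 1632, 1623 and 1583 bp, with mitotic peaks of 260, 165, 272 and 295 bp.

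The widest asynchronous peak without a mitotic overlap spanned 3173 bp on chromosome 1 (143698485 to 143701657), and the nearest mitotic peak lay 2.55 kb away. On chromosome 14, 2 further peaks of this kind (31392684 to 31395347, 2664 bp wide, and 31067314 to 31069415, 2102 bp wide) lay 227.5 and 298.4 kb from the nearest mitotic peak. A 2536 bp peak on chromosome 11 (27151037 to 27153572) was 2946 kb from a mitotic peak. A 2276 bp peak on chromosome 8 (94752528 to 94754803) was 4.24 kb from one.

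The share of asynchronous peaks with a mitotic overlap did not differ detectably between chromosomes. Among the 20 chromosomes with at least 50 asynchronous peaks, the share was highest on chromosome 20 (16 of 87 peaks, 18.4%, 95% interval 10.9 to 28.1) and lowest on the X chromosome (4 of 73 peaks, 5.48%, 95% interval 1.51 to 13.4). In Fisher's exact tests of each chromosome against the rest, 0 of 23 chromosomes passed an adjusted p of 0.05 and 0 had an unadjusted p under 0.05. The X chromosome had the lowest odds ratio, 0.38 (95% interval 0.10 to 1.03, Fisher's exact test, p = 0.0528, adjusted p = 0.965). The intervals span a wide range, so differences of this size were not detectable with these numbers of peaks. The tests treat peaks as independent. On the X chromosome, 2 of the 5 mitotic peaks overlapped no asynchronous peak, so the 4 overlaps are not all independent. Of the 73 asynchronous peaks there, 15 lay in 1 window of 1 Mb.

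**Figure D4:**
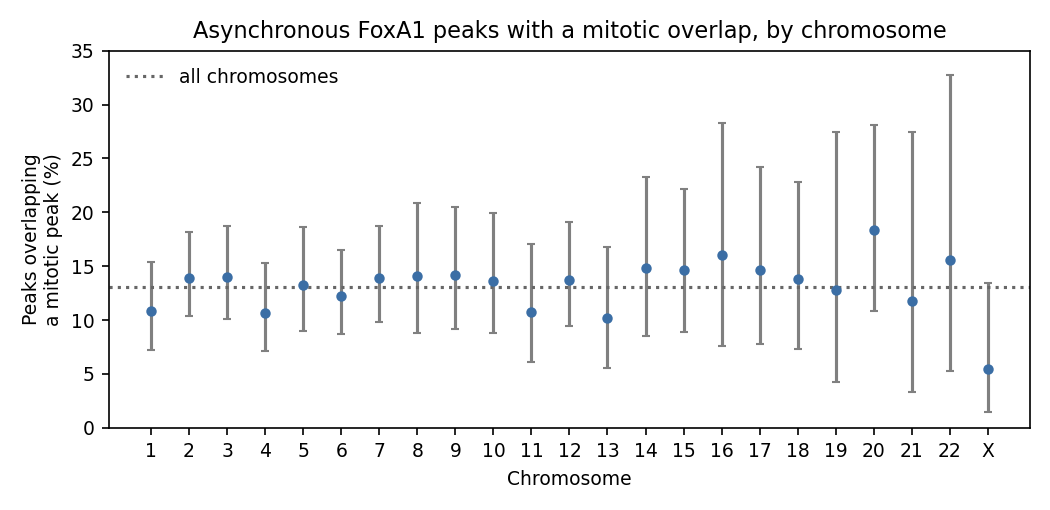
Share of asynchronous FoxA1 peaks with a mitotic overlap (y axis, %) for each chromosome (x axis), with exact 95% intervals and a dotted line at the 13.1% over all chromosomes. The intervals of chromosome 20 (10.9 to 28.1%) and of the X chromosome (1.51 to 13.4%) both include that share.

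Neighbouring asynchronous peaks were not shared with mitotic cells detectably more or less often than isolated ones. Of the 442 asynchronous peaks with another within 10 kb, 49 overlapped a mitotic peak (11.1%, 95% interval 8.31 to 14.4). Of the 3067 isolated peaks, 409 did (13.3%, 95% interval 12.1 to 14.6), which gave an odds ratio of 0.81 (95% interval 0.58 to 1.11, Fisher's exact test, p = 0.200). Stratified by width quartile, an alternative chosen after seeing the data, the odds ratio was 0.75 by the Mantel-Haenszel method (95% interval 0.55 to 1.03, which includes 1). Some of the 442 neighbouring peaks overlap or touch each other, since merging within the list would remove 16 peaks. As 3 mitotic peaks each touched 2 asynchronous peaks, the 49 overlaps are not all independent. Each of the 3 largest clusters held 4 asynchronous peaks. The clusters on chromosome 11 (62764665 to 62775764) and chromosome 2 (54652719 to 54671024) had no mitotic peak, and that on chromosome 9 (83340078 to 83354979) had 1.

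Of the mitotic peaks, 87 (16.0%) overlapped no asynchronous peak. They were narrower than the shared mitotic peaks, with a median of 180 bp (quartiles 141 and 202.5 bp) against 211 bp (quartiles 181 and 246 bp), a difference of 31 bp (95% interval 20 to 53, permutation test, p = 2e-05). None lay within 500 bp of an asynchronous peak, and the closest was 811 bp away. Within 10 kb of an asynchronous peak lay 13 of the 87 (14.9%, 95% interval 8.20 to 24.2), against a mean of 2.51% over rotations (one-sided permutation test, p = 0.00079). That share was carried partly by mitotic peaks lying close together: a single group on chromosome 3 held 6 of the 13. Without mitotic peaks that had another mitotic peak within 10 kb, an alternative chosen after seeing the data, 5 of 70 lay within 10 kb of an asynchronous peak (7.14%, 95% interval 2.36 to 15.9, one-sided permutation test, p = 0.0311).

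**Figure D5:**
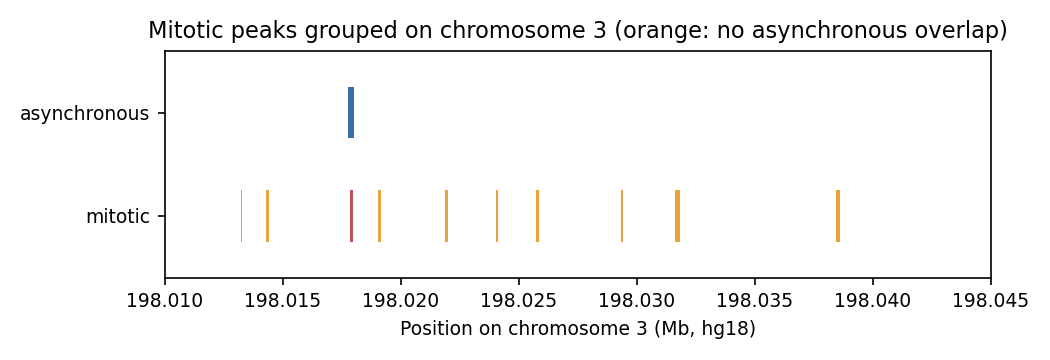
Positions of FoxA1 peaks on chromosome 3 (x axis, Mb, hg18) in the asynchronous list (blue) and the mitotic list (red where it overlaps the asynchronous peak, orange where it overlaps none). Of the 10 mitotic peaks between 198013211 and 198038599, 9 overlap no asynchronous peak, and 1 lies on the only asynchronous peak of the region.

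The widest mitotic peak without an asynchronous overlap spanned 2299 bp on chromosome 6 (58885028 to 58887326), 1411 kb from the nearest asynchronous peak. It was also the widest of the whole mitotic list, and whether it lies in repeated sequence was not examined. The next widest without an overlap were on chromosome 11 (67193351 to 67193786, 436 bp wide), chromosome 12 (30484082 to 30484477, 396 bp), chromosome 11 (66313757 to 66314060, 304 bp) and chromosome 17 (14315170 to 14315449, 280 bp). They lay 89.0, 1309, 220.6 and 53.1 kb from the nearest asynchronous peak.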

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

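No paired analysis was possible because each condition has 1 merged peak list, in which no value belongs to a numbered replicate; for the same reason no replicate could be left out. The alternatives that drop mitotic peaks lying within 10 kb of another, use midpoints within 100 bp or stratify by width quartile were chosen after seeing the data, while the drop of the 2 farthest pairs was named beforehand in the test of that relation but not in the list of settings to vary. Of 34 recomputed values, 30 kept their direction and their side of the threshold or, where there was no test, moved by less than their interval. Keeping the side of a threshold does not mean a like value, since 4 of the 30 moved by over 1.5 times. The share of asynchronous peaks with a mitotic overlap moved to 0.427% when the overlap had to cover at least 50% of both peaks; mitotic peaks are narrower, so few pairs can meet that rule, and the share of mitotic peaks, still above the rotations, was 2.76% against 84.0%. It moved to 7.30% with only mitotic peaks at or above the median width, which removes mitotic peaks by construction, and to 18.5% with only asynchronous peaks at or above the median width; 92.7% and 59.7% of the mitotic peaks then overlapped. Under the 6 other alternatives the share stayed between 12.0% and 13.2% of asynchronous peaks, and between 77.8% and 86.4% of mitotic peaks. The width difference of asynchronous peaks was 39 bp with midpoints within 100 bp, against 80.5 bp. The odds ratio of overlap for peaks with a neighbour turned from 0.81 to 1.02 with neighbours within 50 kb (Fisher's exact test, p = 0.872); the cause was not tested, and neither value passed the threshold. Among mitotic-only peaks, 29.9% lay within 50 kb of an asynchronous peak, against 14.9% within 10 kb, and 7.14% within 10 kb without mitotic peaks near another. The planned comparisons of gene locations, motifs and gene lists were not run, and ranking by width instead of score was no alternative, since width was already the measure. Without depth or heights, a site missed in mitotic cells cannot be told from an unbound one.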

Other observations

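Of the tests below, the rotation test, the fixed-target test of width and the test of neighbouring pairs had their predictions written before their results were seen, although the fixed-target test and the neighbouring pairs were chosen after the peak lists had been examined. The others were chosen after their results were seen. The 1 Mb window with most peaks was on the X chromosome (20173326 to 20896132), where 15 asynchronous peaks lay, 2 of them with a mitotic overlap. On chromosome 14, 4 of the 35 widest asynchronous peaks (each at least 1548 bp) lay between 30767260 and 31625258, a span with 6 asynchronous peaks of median width 2027.5 bp, 2 of them with a mitotic overlap. Shuffling the widths among peaks placed at most 3 of the 35 in any 1 Mb window (10000 shuffles, one-sided permutation p = 1e-04, the smallest possible). The mitotic list had 3 peaks on the Y chromosome, within 57236707 to 57272152 and 56 to 70 bp wide, and the asynchronous list had none there.

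The first pattern is that 457 of 544 mitotic peaks lay on asynchronous peaks. Chance position is argued against by the rotations, which gave at most 35. Residual non-mitotic cells stay open, since about 94% of the cells were in metaphase and the remainder could contribute their strongest interphase sites. Of the asynchronous peaks with a mitotic overlap, 71.2% were above the median width of their list, against the 50% of a random draw. A mark of over 90%, for only the strongest sites coming through, was set after the result was seen and rests on no model. Of the 544 widest asynchronous peaks, 114 (21.0%) had a mitotic overlap. The share was 18.4% in the third width quartile and 18.8% in the widest. Width is not peak height, so these values do not decide, and binding on mitotic chromosomes cannot be told apart from such a residue with positions alone.

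The second pattern is that wider asynchronous peaks more often carried a mitotic peak. Chance meetings along the whole chromosome are argued against by the rotations, which kept the real widths. They gave 0.649 overlapping mitotic peaks on average and 35 at most over all quartiles. The widest quartile alone had 165 overlapping peaks and the narrowest 41. The rotations were not split by width and moved peaks over whole chromosomes. They cannot tell whether a longer interval around a bound site meets more mitotic peaks. The longer interval is argued against as the whole cause by a target of fixed length. With it, the odds ratio of the widest against the narrowest quartile was 1.82 (95% interval 1.18 to 2.84). The odds ratio was 4.73 with any overlap. The fixed target leaves out mitotic peaks that lie inside a wide asynchronous peak but far from its midpoint. With it, the overlapping asynchronous peaks fell from 458 to 345. The fall between the 2 odds ratios thus follows in part from the rule, and 1.82 is not the relation freed of interval length. A biological difference by cycling state stays open and untested, as does a lower sensitivity of the mitotic list, since no depth is known.

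The third pattern is that mitotic-only peaks lay in groups. Another mitotic peak lay within 10 kb of 17 of 87 mitotic-only peaks (19.5%) and of 11 of 457 shared ones (2.41%). Of those 17, 13 came from the 2 largest groups, so the peaks are not independent and no test was made. Without these groups the shares were 5.41% (4 of 74) and 2.19% (10 of 456). The largest group had 10 mitotic peaks, 9 of them without an asynchronous overlap, on chromosome 3 (198013211 to 198038599), and the next had 4 on chromosome 15 (19189995 to 19191115), 10046 kb from the nearest asynchronous peak. The chromosome 3 peaks were 71 to 189 bp wide with a median of 128.5 bp, and the single asynchronous peak there was 262 bp wide, with 0.741% of asynchronous peaks narrower. Reads piled up in repeated sequence, and DNA copies of a spliced transcript whose fragments map to exons, are candidate explanations that cannot be told apart here, because the hg18 sequence, its exons and the input libraries were not used; binding specific to mitosis also stays open and untested. The same explanation by copies of a transcript stays open, and untested, for the mitotic peak of 1722 bp on chromosome 14 (37130322 to 37132043), the widest shared mitotic peak, which was 93.7% as wide as its asynchronous peak and was followed by one of 925 bp on chromosome 8.

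One hypothesis was that neighbouring sites keep FoxA1 in mitosis together. Among 232 neighbouring pairs of asynchronous peaks within 10 kb, both peaks overlapped a mitotic peak in 5 pairs and 1 of the pair did in 41. Overlaps were shuffled among peaks of the same width decile. This gave 3.02 pairs with both overlapping on average and 10 at most (one-sided permutation test, p = 0.166). The count of 5 did not pass the threshold. It lay above the mean, but 3 mitotic peaks each touched 2 asynchronous peaks, so 3 of the 5 pairs rest on 1 mitotic peak each. The shuffles do not carry this link and were not repeated without it, so the test does not decide and the hypothesis stays open.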
